A study of Mus musculus with 2 samples.

How the data were processed

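Single cells of mouse intestinal organoids, epithelial cultures kept in medium with the growth factors EGF, Noggin and R-spondin, were profiled with droplet-based 3-prime RNA sequencing, in which each captured transcript carries a unique molecular identifier (UMI). Per the labels, the organoids came from wild-type C57BL/6 mice, and 1 library was made from organoids at day 3 and 1 at day 5. Per the labels' protocols, the medium held 20% Wnt3a-conditioned medium and 10 µM of the ROCK inhibitor Y-27632 up to day 3, with 3 µM of the GSK3B inhibitor CHIR99021 up to day 1, and none of these from day 3 to day 5. The day of culture and the medium therefore differ together between the libraries.

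The authors deposited a table of UMI counts per gene and cell for 15745 genes and 1863 cells, made with Cell Ranger 1.3.0 on build mm10 per the submitters' processing notes. The filters that chose these genes and cells are not given in the sources used here. The authors also deposited log2 values of the same genes and cells. From the values, each is the log2 of the UMI count divided by the cell's size factor, plus 1, and the size factor is the cell's total over the mean total of all cells. The prefix of each cell's column named its day. Gene identifiers were matched to symbols in 15681 cases, and the 64 genes left without a symbol held 0.0194% of all UMIs. Positions come from GENCODE M21 on GRCm38, the assembly that mm10 names.

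The day 3 library held 798 cells and 28764033 UMIs, with a minimum of 17601 and a median of 32063.5 UMIs per cell. The day 5 library held 1065 cells and 17349076 UMIs, with a minimum of 6777 and a median of 13549 UMIs per cell. The lowest cell thus held 0.549 of the library's median at day 3 and 0.500 at day 5, and the depth gap and both minimums can set shares of cells. As a check, the day 3 minimum was applied to the day 5 cells.

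UMI counts were summed over all cells of a library and given as counts scaled to a library of 1000000 UMIs (CPM), with exact Poisson 95% intervals. The log2 ratio of day 5 over day 3 used 0.5 UMI added to each sum. There were no replicates, so no test between days was possible and no p-value is given. Intervals cover counting error only and say nothing of differences between cultures. Analyses ran in Python with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scanpy 1.11.5, and figures were drawn with matplotlib 3.10.9.

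Before the data were examined, 26 gene lists of cell types and pathways were fixed, with a rule for the genes to name. The rule takes the 10 genes with the highest and the 10 with the lowest log2 ratio among genes with at least 100 CPM in the higher library and at least 10 UMIs in the lower one. It leaves out mitochondrial, ribosomal protein and predicted genes, and genes whose direction differed in the mean of the authors' log2 values. It adds 24 focal genes of stem, Notch, YAP, Paneth and absorptive cells, and the 2 highest and 2 lowest members of each list. Some genes that this rule takes are not reported here. Within a compared cell class it takes the 5 highest and 5 lowest genes by the same limits. A list member counted as higher or lower at a ratio of at least 1.5-fold with Poisson intervals that did not overlap. The median log2 ratio of the members with at least 10 UMIs over both libraries was set against 10000 random lists of the same size matched on mean CPM in 20 bins. The interval of a list median came from 1000 redraws of the counts.

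The median log2 ratio of the 12782 genes with at least 10 UMIs was -0.33 with CPM and -0.02 with TMM factors of edgeR 4.0.16, a shift of 0.31. The medians of the matched random lists carry the same offset and stand beside the list medians. On counts drawn from a Poisson model for the comparison of all cells, the rule was tried on 12782 genes. It called 100% of 50 genes set to 2-fold higher, 96% of 50 genes set to 0.5-fold and 0.207% of 12582 unchanged genes. The rule's intervals use the same model, and the draws hold no clumping of UMIs in single cells. These shares are therefore not error rates for the measured counts.

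Cells of both libraries were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method (resolution 1, igraph 0.11.9) after scaling to 10000 UMIs per cell. A cluster's leading genes were ranked by fold over all other cells among genes with a UMI in at least 25% of its cells. A cluster was called X-like where at least 3 of its 25 leading genes were fixed markers of that type and no other type had more among the first 10. A cluster in which at least 3 markers of more than 1 secretory type led was called mixed secretory, and all others stayed unnamed. Scrublet, run per library with an expected share of 6%, called 2 doublets at day 3 and 6 at day 5, which were kept. With so few calls, doublets cannot be taken as removed.

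For shares of cells with a UMI, co-detection and cell-to-cell spread, each cell was thinned at random to 9800 UMIs. This left out 0 cells at day 3 and 183 at day 5, which are 17.2% of that library, and 85.2% of those were Enterocyte-like. Shares carry exact Clopper-Pearson intervals. The background of a gene is its thinned share in a class that should lack it, with classes taken from each library clustered alone. A transcript count of 0 was given an upper limit of 3 UMIs in its library, and a share of 0 cells one of 3 cells. The limit of 3 UMIs takes UMIs as independent and does not cover their clumping in few cells. Defensin genes (Defa), the Sprr2a copies, Lyz1 with Lyz2, and Hspa1a with Hspa1b are near-identical copies whose reads the counting could split or drop, so their single values are uncertain.

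Alternatives covered the library scaling, the weighting of cells, the authors' log2 values, filters on genes and cells, doublets, cluster settings and thinning depth. Added after seeing the data were list and gene ratios without the Enterocyte-like clusters, sub-clusters of the mixed secretory cluster, values within it, named genes without the cell that held most of their UMIs, and Proliferating-like values without the cluster led by Ero1l and Ankrd37. All columns of both tables were used.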

Results

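Transcripts of single cells from mouse intestinal organoids were counted at day 3 and at day 5 of culture, with 1 library per day. The day 3 library held 28764033 UMIs in 798 cells with a median of 4997 detected genes and 4.49% mitochondrial UMIs, and the day 5 library 17349076 UMIs in 1065 cells with a median of 2755 genes and 6.47% mitochondrial UMIs. The series is about how an organoid that starts without a pattern breaks symmetry and forms its cell types, so the comparison asks which cell type programmes differ between these days. No replicates exist, so each difference below is between these libraries, with intervals for counting error only.

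Over all cells, antimicrobial and absorptive genes were far higher at day 5 and genes of regenerating epithelium far lower. Reg1 (ENSMUSG00000059654), a secreted lectin-like protein of the gut, stood at 0.869 CPM (0.562 to 1.28) at day 3 and 5505 CPM (5469.8 to 5539.7) at day 5, a log2 ratio of 12.60. Reg3b and Reg3g, bactericidal lectins, had log2 ratios of 11.13 and 6.89. Genes are ranked here by the fixed rule, with at least 100 CPM in the higher library and at least 10 UMIs in the lower one. The other genes with the highest ratios by it were Mme, a membrane peptidase (8.22), Slc6a20a, an amino acid transporter (7.39), Spink1, a protease inhibitor (7.21), Cyp3a11, a drug-metabolising enzyme (7.12), Rdh7, a retinol dehydrogenase (6.94), and the lipoprotein genes Apoa4 (6.89) and Apoa1 (6.86). At the other end by the same rule stood Sprr2a3, a small proline-rich protein of stressed epithelium. It was at 178 CPM (173 to 183) at day 3 and 2.25 CPM (1.60 to 3.07) at day 5, a log2 ratio of -6.29. Next came the galectin gene Lgals3 (-4.50), Clu (ENSMUSG00000022037), which encodes clusterin (-4.14), Anxa3 (-3.30), the glutathione peroxidase gene Gpx2 (-3.10), Msln, which encodes mesothelin (-2.68), S100a6 (-2.63), Tnfrsf12a, the TWEAK receptor (-2.55), Ero1l, an oxidase of the endoplasmic reticulum (-2.53), and Srm, which makes spermidine (-2.51). Per the annotation, Reg1 lies on chromosome 6 from 78422711 to 78428667 and Clu on chromosome 14 from 65968483 to 65981547 (GRCm38), both protein-coding genes. Among the focal genes, Lgr5 lies on chromosome 10 from 115450311 to 115587780, Yap1 on chromosome 9 from 7931999 to 8004596 and Dll1 on chromosome 17 from 15367354 to 15376872.

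Genes of absorptive enterocytes, the nutrient-absorbing cells of the villus, were all higher at day 5. All 15 measured members of the Enterocyte list counted as higher, with a median log2 ratio of 3.94 (3.92 to 3.98), against -0.21 for matched random lists, percentile 100. The lactase gene Lct (7.45, exact interval 5.91 to 10.83, from 2 UMIs at day 3) and Apoa4 (6.89) had the highest ratios, and Mttp, which loads lipid onto lipoproteins (2.20), and Alpi, the intestinal alkaline phosphatase (2.50), were among the lowest. Fabp1, a fatty acid carrier, was at 263 CPM and 4045.9 CPM. In the Reg family 4 of 5 members were higher (median 11.13, or 10.26 with a member at 0 set to its bound). Reg3a had 0 UMIs at day 3 and was at least 1225-fold higher at day 5, whereas Reg4, a marker of secretory cells, had a log2 ratio of 0.094, or -0.21 without the cell with most of its UMIs, and 0.66 with Enterocyte-like cells left out, where it counted as higher. Of 11 genes of fatty acid oxidation and ketogenesis, 6 were higher and 0 lower (10 and 0 under TMM), with a median of 0.92 (percentile 99.98), led by Pdk4 (5.03, exact interval 2.99 to 10.94, from 1 UMI at day 3) and the peroxisomal enzyme gene Ehhadh (2.67). The Villus tip list had 4 members with at least 10 UMIs and a median of 2.38, but -0.77 with no minimum of UMIs. Of these, Apoa4 and the transcription factor gene Creb3l3 (4.95) were higher and Ada, which degrades adenosine, was lower (-1.34). The UMI minimum bears on these values: of the day 5 cells, 47.3% were in Enterocyte-like clusters, but 10.9% of the 320 cells that reached the day 3 minimum of 17601 UMIs. With those cells alone at day 5, the Enterocyte median was 2.87.

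Markers of fetal-like and regenerating epithelium were lower at day 5 without exception among the 11 measured members. Their median log2 ratio was -2.92 (-3.44 to -2.65, percentile 0), or -2.68 with a member at 0 set to its bound, and it was -2.80 with Enterocyte-like cells left out. Ly6a, the surface protein Sca-1 that marks regenerating crypts, was at 99.2 CPM (95.5 to 103) at day 3 and 5.48 CPM (4.43 to 6.69) at day 5. The alarmin gene Il33 had a ratio of -2.22 and the keratin gene Krt7 one of -2.49. Target genes of YAP, the Hippo pathway's transcriptional coactivator, had a median of -1.43 (-1.73 to -1.11, percentile 0), with 11 of 15 members lower and 0 higher under CPM, and 8 lower and 2 higher under TMM. With members at 0 set to their bound the median was -1.27. The secreted matrix protein gene Ccn2 was at 15.0 CPM and, with 2 UMIs, 0.115 CPM, a log2 ratio of -6.71 (exact interval -10.08 to -5.16), and its relative Ccn1 was at 76.1 and 23.1 CPM. Ankrd1 had 0 UMIs at day 5 and was at least 20.1-fold lower. Nuak2 (0.57) and Gadd45a (0.47), at the upper end of the list, counted as neither under CPM. Yap1 itself was at 33.1 CPM (31.0 to 35.3) and 18.6 CPM (16.6 to 20.7).

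Stem cell markers split. Lgr5, the R-spondin receptor of crypt base stem cells, was at 16.0 CPM (14.6 to 17.5) and 18.4 CPM (16.5 to 20.6), a log2 ratio of 0.21 (exact interval -0.0045 to 0.41) that was -0.17 with each cell weighed alike. With Enterocyte-like cells left out, Lgr5 was at 16.0 and 27.8 CPM and counted as higher (0.80). Smoc2 and Gkn3 had ratios of -0.074 and -0.056, closer to 0 than the TMM shift of 0.31, so that their sign flips under TMM. Ascl2, a stem cell transcription factor, was at 10.2 and 4.55 CPM (-1.15), Axin2, a feedback target of Wnt, at 35.3 and 13.7 CPM (-1.36), and the ion transporter gene Slc12a2 at 223 and 79.4 CPM (-1.49). Of the 11 Stem members, 7 were lower and 0 higher (5 and 0 under TMM), with a median of -0.61 (-0.86 to -0.50) at percentile 17.5 of random lists. Olfm4, a common marker of these cells in the small intestine, had 7 and 12 UMIs in all. Wnt target genes had a median of -1.35 (-1.48 to -1.12, percentile 0), with 9 of 13 lower and 0 higher, among them the adhesion receptor gene Cd44 (-2.31), the cyclin gene Ccnd1 (-1.79) and Tcf7 (-2.76). With Enterocyte-like cells left out, the medians were -0.25 for Stem, with 1 member higher and 3 lower, and -0.76 for Wnt targets, with 1 higher and 7 lower. Proliferation genes had a median of -1.11 (percentile 0), with 13 of 15 lower (10 under TMM), such as Rrm2, which makes deoxynucleotides (-1.67), and Mki67 at 137 and 49.9 CPM. Without Enterocyte-like cells that median was -0.53, with 6 members lower.

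Among Notch signalling genes, the ligand genes Dll1 and Dll4 had ratios of 0.18 and 0.24, with Dll1 at 9.11 CPM (8.04 to 10.3) and 10.3 CPM (8.86 to 11.9), and Notch1 stood at 8.93 and 8.88 CPM, a ratio of -0.0076 that was 0.31 under TMM. Hes1, a repressor that Notch induces, was at 133 CPM (128 to 137) and 212 CPM (205 to 219), the single member of 6 in the receptor and target list that was higher. That list had a median of -0.060 (0.25 under TMM, percentile 73.3), with Notch2 lower (-0.63), which no longer counted under TMM. Of 8 ligand and secretory commitment genes, 3 were lower and 0 higher (median -0.66, percentile 15.2). Those were Jag1 (-1.07), Jag2 (-2.31) and Neurog3, the endocrine commitment factor, which had 125 UMIs at day 3 and 0 at day 5, at least 25.1-fold lower. The 125 UMIs lay in 18 cells, 91.2% of them in 10 cells. That bound takes UMIs as independent, so it does not cover the chance of missing a few such cells at day 5. Atoh1, the factor of secretory commitment, was at 3.75 CPM (3.08 to 4.53) and 3.11 CPM (2.34 to 4.06), with overlapping intervals and a ratio of -0.26 that was 0.049 under TMM. BMP targets had a median of -0.94 (percentile 3.34), with 3 of 6 lower, the inhibitors of differentiation Id1 (-1.15), Id2 (-0.99) and Id3 (-2.05).

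Paneth cell genes, which encode antimicrobial peptides of the crypt base, were higher at day 5 in 11 of 14 members, with a median of 2.70 (2.49 to 2.87, percentile 100). Defa24, an alpha-defensin gene, was at 415 CPM (407 to 422) and 1924.5 CPM (1904.0 to 1945.3), Lyz1, which encodes lysozyme, at 26.7 and 41.6 CPM (a ratio of 0.64, or 0.20 without the cell that held 26.2% of its day 5 UMIs), and Mmp7, which processes defensins, at 20.5 and 17.6 CPM, a ratio of -0.22 that was 0.089 under TMM. Most of these UMIs came from few cells: the 10 cells with the most Defa24 held 70.4% of its UMIs at day 3 and 57.1% at day 5. In the mean of the authors' log2 values, which weighs each cell alike on a log scale, the Paneth median was 0.037 and Lyz1 was lower at day 5 (-0.059). Of 12 Goblet genes, 5 were higher, 1 was lower and the median was 0.13 (percentile 95.5), but -0.030 in the mean of the authors' log2 values. The mucin gene Muc2 (3.13) and Zg16, a lectin of mucus (3.36), were the highest, and Agr2, a chaperone of mucin folding, was lower (-1.02). With Enterocyte-like cells left out 8 were higher and 0 lower, and Agr2 (-0.44) no longer counted. Enteroendocrine genes went both ways, with 6 of 17 higher and 5 lower (median -0.33, percentile 46.7), and the median was 0.46 with each cell weighed alike. Gcg, the glucagon gene, had a ratio of 3.00, but 98.3% of its 1265 UMIs at day 5 lay in 1 cell, and without that cell, a choice made after seeing the data, the ratio was -2.87. Sst, the somatostatin gene, had 0 UMIs at day 3 and was at least 40.9-fold higher at day 5, or 24.3-fold without the 1 cell that held 40.5% of its UMIs. Peptide YY transcripts (Pyy) had 56 UMIs at day 3, 89.3% of them in 1 cell, and 0 at day 5, at least 11.3-fold lower, or 1.21-fold without that cell. Of 7 measured Tuft genes, 1 was higher, the leukotriene synthase gene Ltc4s (1.46), with a median of 0.73 (percentile 95.3), and Dclk1 had 5 UMIs in each library.

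**Figure D1:**
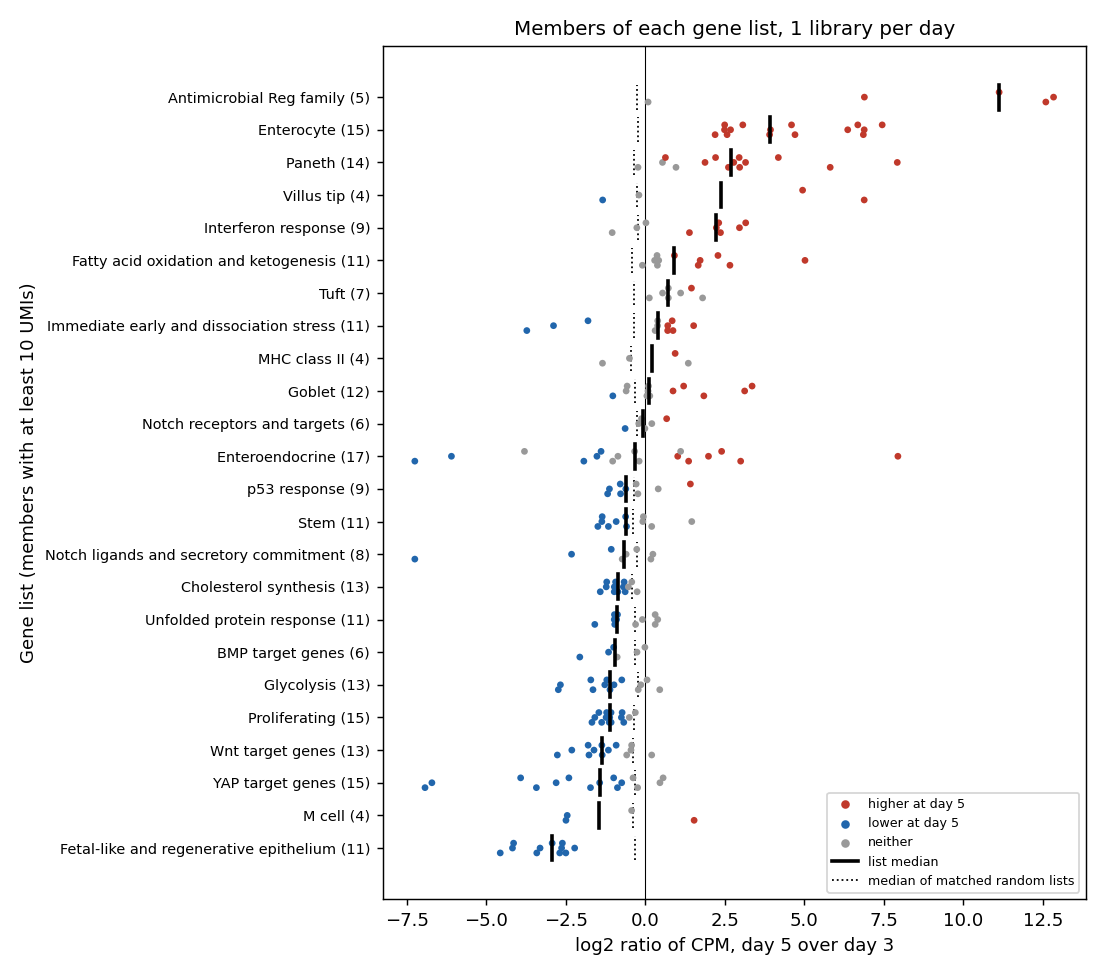
Log2 ratio of CPM, day 5 over day 3, on the horizontal axis for each member with at least 10 UMIs of the lists with at least 4 such members (rows), 1 point per gene, coloured by whether it counted as higher, lower or neither. Black bars are list medians and dotted bars the medians of matched random lists; the Reg family sits at 11.13 and the Enterocyte list at 3.94, and the fetal-like list lies lowest at -2.92, with members at 0 UMIs in a library placed by the 0.5 UMI added to each sum.

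Metabolic and stress genes also differed. Glycolysis genes had a median of -1.10 (percentile 0), with 9 of 13 lower (under TMM 8 lower and 1 higher, the isomerase gene Gpi1), and with Ldha, lactate dehydrogenase, at 1583.4 and 657 CPM and the glucose transporter gene Slc2a1 at 40.7 and 6.40 CPM. Gapdh was at 1690.3 and 1762.8 CPM, a ratio of 0.061 that was -0.56 with Enterocyte-like cells left out. Of 13 cholesterol synthesis genes, 10 were lower (6 under TMM), with a median of -0.86 (percentile 1.01), among them Lss (-1.41). Genes of the unfolded protein response had a median of -0.87 (percentile 0.845), with 6 of 11 lower and 0 higher, but 4 lower and 3 higher under TMM. In the p53 list 5 of 9 were lower and 1 higher (2 and 2 under TMM), with a median of -0.61 (percentile 15.0), where Bax was lower (-1.18) and the death receptor gene Fas higher (1.42). With Enterocyte-like cells left out 5 were lower and 0 higher, and Fas was at 0.30. In the immediate early and dissociation stress list the median was 0.40 and the mean -0.24, since Dusp1 (1.53), Egr1 (0.88), Fosb (0.85) and others were higher while the heat shock genes Hspa1a, Hspa1b and Hspb1 were lower. Their ratios were -1.80, -2.88 and, with 3 UMIs at day 5, -3.72 (exact interval -6.24 to -2.33). That list held 5 higher and 3 lower of 11 under CPM, 8 and 3 under TMM, and its median was -0.12 with Enterocyte-like cells left out.

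Interferon response genes had a median of 2.24 (percentile 100), with 6 of 9 higher, at low levels such as 1.36 and 6.46 CPM for Irf7. With Enterocyte-like cells left out 2 of 9 were higher. Markers of other cells were scarce. Of the Immune list, 2 members were measured, Ccl5 with 0 and 12 UMIs (at least 6.63-fold higher) and Cd68 with 44 and 8 (median 1.86, or 0.54 with the member at 0 set to its bound). Of the Stromal and endothelial list, Vim had 25 UMIs and 1 UMI (log2 ratio -3.36, exact interval -9.27 to -1.30) and Pecam1 4 and 10 (median -0.70). The 4 measured genes of MHC class II, which presents peptides to T cells, had a median of 0.23 (percentile 83.6), with H2-DMa higher (0.94). The 4 measured M cell genes had a median of -1.44 (percentile 0.36), where Anxa5 (-2.49) and Marcksl1 (-2.45) were lower and the chemokine gene Ccl20 higher (1.54).

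Clustering of all cells gave 12 clusters, and in 11 of them at least 95% of the cells came from 1 library. In these, cluster and library coincide, so their sizes are not compared between days. Clusters 1 and 2 were Enterocyte-like and held 3 day 3 and 504 day 5 cells. Proliferating-like cells lay in clusters 7 and 11, nearly all from day 3, and in cluster 5, from day 5. Cluster 11 was led by Ero1l and Ankrd37, genes induced by low oxygen, beside its 3 cell cycle markers. Cluster 8 was Stem-like, led by Rgcc, Ifitm3 and Ascl2, with 124 day 3 cells. Clusters 3, 4, 6, 9 and 12 stayed unnamed and held 50.5% of day 3 and 30.1% of day 5 cells. Cluster 4, with 191 day 3 and 9 day 5 cells, was led by Clu, Msln, Ly6a and Anxa1, and cluster 9, with 101 day 5 cells, by Edn2 and Depp1. Clustered alone, the day 3 library also had a small Enterocyte-like cluster of 61 cells, 7.64% of the library, and the day 5 library had Enterocyte-like clusters with 34.5% of its cells. Clustered alone, Stem-like clusters appeared in both libraries, with 86 and 62 cells at day 3 and 113 cells (10.6%) at day 5, the latter led by Ttr and Marcksl1.

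**Figure D2:**
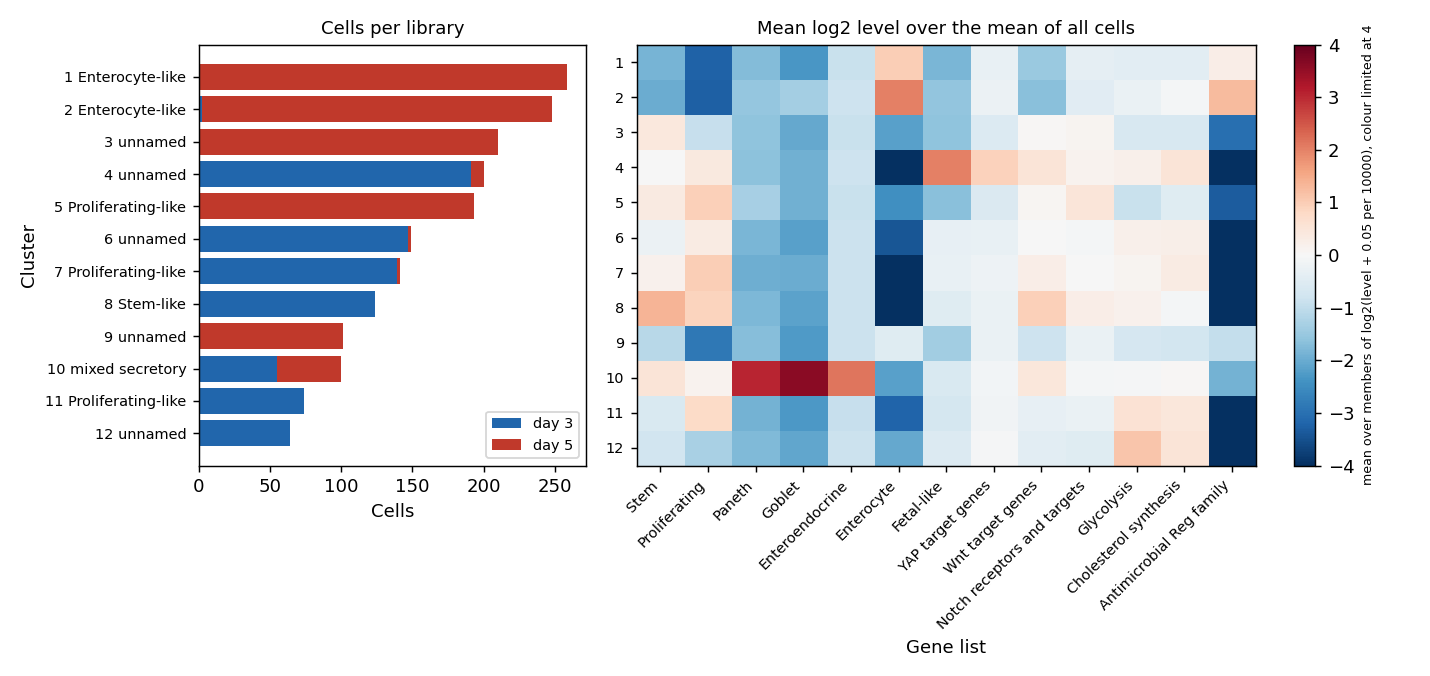
Cells per library in each of the 12 joint clusters (left, stacked bars, number of cells) and the mean log2 level of 13 gene lists in each cluster over all cells (right, colour, rows are clusters). Cluster 10 is the single cluster with many cells of both libraries, 55 of day 3 and 45 of day 5, and holds the Paneth, Goblet and Enteroendocrine signal; the fetal-like list is highest in cluster 4.

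Cluster 10, mixed secretory, drew on both libraries and held 6.89% of day 3 cells (5.23 to 8.88, Clopper-Pearson) and 4.23% of day 5 cells (3.10 to 5.61). Its defining genes differ between the days, so these shares carry no direction. Within it, an added comparison after seeing the data, Paneth genes were higher per UMI at day 5 in 12 of 14 members (median 3.43) and Goblet genes in 9 of 12 (median 0.79). Defa24 was at 5012.2 CPM (4917.3 to 5108.4) in the day 3 cells and 37706 CPM (37289 to 38127) in the day 5 cells of this cluster, and Muc2 at 87.8 CPM (75.6 to 101) and 1198.9 CPM (1125.5 to 1275.8). Neurog3 was at 56.1 CPM (46.5 to 67.2) with 119 UMIs, and 0 UMIs in the day 5 cells, at least 15.5-fold lower. Only 23.6% of the day 3 cells of this cluster had a Neurog3 UMI, and the bound does not cover such clumping. Dll1 and Atoh1 had overlapping intervals, 38.7 CPM (30.8 to 48.0) and 49.5 CPM (35.5 to 67.2) for Dll1. Mki67 was at 126 and 50.7 CPM. Sub-clusters of these cells included a Paneth-like group with 0 day 3 and 22 day 5 cells, a Goblet-like group with 14 and 4, and an Enteroendocrine-like group with 9 and 5. An unnamed group led by Neurog3 held 14 and 1 cells, and one led by Rgcc 18 and 3. The Paneth-like group comes from 1 library, so its 0 does not show that day 3 lacked such cells. Lyz1 had a UMI in 61.8% of day 3 and 66.7% of day 5 cells of cluster 10. An Enterocyte-like sub-cluster held 0 and 10 cells, with 7 enterocyte markers and 0 Paneth, Goblet or Enteroendocrine markers among its 25 leading genes.

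Proliferating-like cells were the only named class with at least 50 cells per library, 213 at day 3 (clusters 7 and 11) and 195 at day 5 (cluster 5, and 2 cells of cluster 7). Within it, the fetal-like list was again lower, with 7 of 8 members and a median of -2.72 (-3.35 to -2.29), and Clu was at 121 CPM (113 to 129) and 8.55 CPM (6.11 to 11.6). Glycolysis genes were lower in 12 of 13 members (median -1.06) and cholesterol synthesis genes in 10 of 13 (median -1.01). Of the day 3 cells, 74 belong to cluster 11, led by Ero1l and Ankrd37. Leaving it out, a choice made after seeing the data, left 139 day 3 cells, with 10 glycolysis genes lower (median -0.91) and 10 cholesterol genes lower (median -0.99). The lowest ratios by the fixed rule were those of Clu (-3.81), Ero1l (-3.05), the glycolytic aldolase gene Aldoa (-2.65), the desaturase gene Scd2 (-2.41) and Gpx2 (-2.39). Without cluster 11 the ratio of Ero1l was -1.87 and that of Aldoa -2.27. YAP targets had 4 of 11 members lower and 0 higher (median -1.06), with Yap1 at 29.4 and 16.0 CPM. Of 10 Stem genes, 3 were higher and 0 lower (median 0.53, 0.16 to 0.68), and 2 higher and 1 lower without cluster 11 (median 0.25), with Lgr5 at 10.0 and 32.7 CPM. The 124 day 3 cells of the Stem-like cluster 8, with Lgr5 among its leading genes, lie outside this class. Their mean log2 level of the Proliferating list over all cells was 0.88, near that of clusters 5 (0.95) and 7 (0.99). The naming thus takes cycling Stem-like cells from the day 3 side only, so the Stem and Lgr5 differences may not be between like cells. Notch receptors and targets had 3 of 6 higher (median 0.76), Hes1 at 105 and 202 CPM, the glycosyltransferase gene Lfng at 3.38 and 9.83 CPM, and Nrarp at 15.9 and 28.4 CPM. By the fixed rule, with at least 100 CPM in the higher library and at least 10 UMIs in the lower one, 5 genes ranked highest. These were the sucrase gene Sis (4.66), Reg3g (4.16), Adh1 (3.87), Selenop (3.59) and Aoc1 (3.03). Without cluster 11 these ratios were 6.30, 4.13, 5.15, 4.69 and 3.66. The Reg family, whose members can fall under the UMI limit, had a median of 5.94, with 4 of 5 members higher. Of 14 enterocyte genes, 10 were higher and 1, Alpi (-0.69), lower (median 1.23), and 11 higher and 0 lower without cluster 11 (median 1.87). The p53 list had a median of 0.58 here (percentile 99.8), with 2 of 9 higher and 1 lower. Without cluster 11 it was 0.90, with 5 higher and 1 lower, but with each library clustered alone -0.22. Paneth genes were higher in 6 of 9 members (median 1.71, percentile 100), with Defa24 at 48.1 and 230 CPM. Free RNA from other cells remains open for the Enterocyte, Paneth and Reg lists. Reg1 stood at 2.22 UMIs per 10000 in the day 5 cells of cluster 5 and at 165 in those of cluster 2.

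Shares of cells with a UMI at equal depth repeated several of these differences cell by cell. After thinning, Ly6a was seen in 32.6% of day 3 cells (29.3 to 36.0) and 1.47% of day 5 cells (0.787 to 2.51), against 23.0% and 0.45% of Enterocyte-like cells, and Clu in 54.1% (50.6 to 57.6) and 6.58% (5.03 to 8.42). In Enterocyte-like cells Clu was seen in 24.6% and 7.21%, so its day 5 share over all cells does not exceed that class. Its day 5 UMIs were not spread evenly, with 234 in 55 cells of 1 cluster and 127 in the other cells. Ccn2 was seen in 6.89% of day 3 cells (5.23 to 8.88) and in 0 of 882 day 5 cells, which allows a share of up to 0.340%, against 1.64% of Enterocyte-like cells at day 3. Yap1 had a UMI in 24.9% (22.0 to 28.1) and 15.0% (12.7 to 17.5) of cells, against 16.4% and 18.0% of Enterocyte-like cells, so its day 5 share lay no higher than in that class. Lgr5 was seen in 11.8% (9.62 to 14.2) and 10.5% (8.60 to 12.8), against 6.56% of 61 Enterocyte-like cells at day 3 and 0.45% of 222 at day 5. Dll1 was seen in 8.02% (6.23 to 10.1) and 9.30% (7.46 to 11.4), no more than in Enterocyte-like cells of each library clustered alone (9.84% and 10.8%). In the joint clusters it was seen in 4.69% and 5.29% of Proliferating-like and 29.1% and 38.9% of mixed secretory cells. Defa24 was seen in 39.5% and 56.3% of all cells and in 31.1% and 53.6% of Enterocyte-like ones, with overlapping intervals, so its share over all cells is read as background. Atoh1, by contrast, was seen in 32.7% and 33.3% of mixed secretory cells of the joint cluster. In Enterocyte-like cells of each library clustered alone it was seen in 0.45% at day 5 and 0 of 61 at day 3, which allows up to 4.92%. Median depths before thinning were 23772 and 11857 UMIs in the Enterocyte-like cells and 32582 and 16613 in the others. Krt20, a keratin of mature villus cells, was seen in 6.27% and 27.0%, against 3.36% and 3.48% of Proliferating-like cells of each library clustered alone. Median depths of those Proliferating-like cells were 37957 and 20955.5 UMIs, against 30768 and 13334 in the others. Without thinning the shares of Lgr5 were 26.7% and 16.3%, of Yap1 61.5% and 24.2%, of Dll1 22.7% and 14.3%, of Clu 82.7% and 8.36%, of Ly6a 56.0% and 2.35%, of Ccn2 16.2% and 0.188%, and of Krt20 15.7% and 38.6%.

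**Figure D3:**
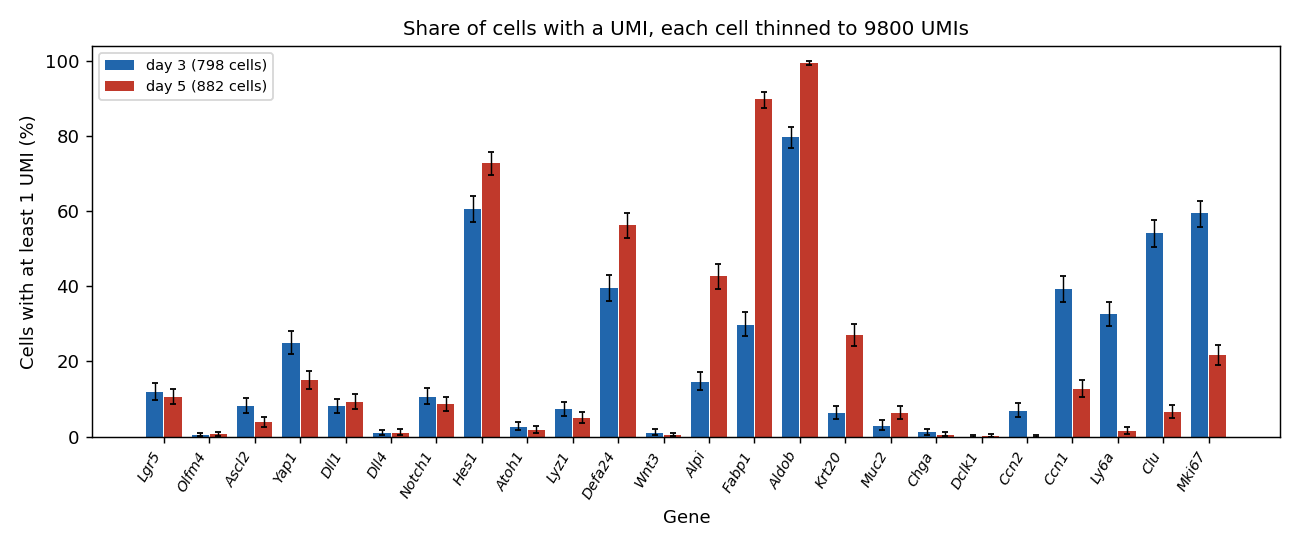
Percent of cells with at least 1 UMI of each focal gene (vertical axis) after thinning each cell to 9800 UMIs, for 798 day 3 and 882 day 5 cells. Error bars are exact 95% binomial intervals, which cover counting error only. Clu lies at 54.1% and 6.58%, Fabp1 at 29.8% and 89.8%, and Lgr5 at 11.8% and 10.5%. Fabp1 was seen in 12.6% and 74.8% of Proliferating-like cells of each library clustered alone, and in 33.3% and 72.5% of those of the joint clusters.

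Within each library, Lgr5 and the stem cell factor Ascl2 were seen together more often than by chance, in 18 cells against 7.66 expected at day 3 (observed over expected 2.35, 1.39 to 3.72) and in 11 against 3.59 at day 5 (3.07, 1.53 to 5.49). Lgr5 was seen with Alpi less often, with values of 0.363 (0.118 to 0.847) and 0.151 (0.0555 to 0.329), and at day 5 with Krt20 less often (0.12, 0.0247 to 0.349) and with Mki67 more often (1.69, 1.17 to 2.36). Dll1 was seen with Lyz1 more often on both days (2.15, 1.03 to 3.95, and 2.75, 1.37 to 4.92) and with Muc2 at day 5 (3.32, 1.94 to 5.32). Lgr5 too was seen with Lyz1 more often at day 3 (1.90, 1.01 to 3.25), while at day 5 the interval held 1 (1.99, 0.908 to 3.77). For Dll1 with Lgr5 the interval held 1 on both days (1.06, 0.458 to 2.09, and 0.694, 0.255 to 1.51). Of 60 pairs with at least 3 expected cells, counted once per day, 7 lay above 1, 3 below and 50 neither, with no correction for their number.

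Dll1, Hes1 and Atoh1 varied more between cells than most genes of like mean. The Fano factor, variance over mean of thinned UMIs, of Dll1 lay at percentile 98.0 of the 200 genes nearest in mean at day 3 and at 95.5 at day 5. Atoh1 lay at 98.0 and 99.0, Hes1 at 97.5 and 89.5, and Lgr5 at 97.5 and 97.0. Yap1 lay at 78.0 and 74.5, and Notch1 at 23.5 and 39.5. The YAP target gene Ccn1 lay at 97.0 and 100, and Ccn2 at 99.5 at day 3. Other focal markers lay as high, such as Alpi (99.5 and 97.0), Clu (98.0 and 99.5) and Mki67 (96.5 and 96.0), while Olfm4 lay at 15.0 and 54.0. A high percentile is thus not particular to the Notch genes.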

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

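The alternatives that leave out the Enterocyte-like clusters, the clusters led by Ero1l and Ankrd37, or the cell with most UMIs of a gene, were chosen after seeing the data. Leaving out called doublets reversed no ratio that counted as higher or lower in all cells, among 129 named genes and 26 list medians. TMM and totals without the 20 most abundant genes shift all ratios alike, by 0.31 and 0.021, too little to reverse a gene past 1.5-fold. Of genes that counted as neither, 11 changed sign with TMM, as did the Notch receptor list (0.25). The Enterocyte median (3.94) was 4.26 with TMM, 4.03 with each cell weighed alike, 1.97 in the authors' log2 values, 3.84 in cells with at most 10% mitochondrial UMIs, 4.46 as a mean of members and 2.32 without Enterocyte-like clusters. The Paneth median (2.70) was 3.02 with TMM, 0.037 in the log2 values, 2.96 with no minimum of UMIs and 3.00 without Enterocyte-like clusters. The Stem median (-0.61) was -0.30 with TMM, -0.93 with cells weighed alike, -0.26 in the log2 values and -0.25 without Enterocyte-like clusters. The fetal-like median (-2.92) was -2.61, -3.74 and -0.60 with TMM, cells weighed alike and the log2 values. The YAP target median (-1.43) was -0.059 in the log2 values and -2.10 as a mean. Log2 values are smaller for low genes by construction, since 1 is added to each value.

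The share of day 3 cells in Enterocyte-like clusters was 0.376%, and 7.64% with that library clustered alone. At day 5 it was 47.3%, and 31.3% at resolution 0.5, 34.5% with that library alone, 35.6% with doublets left out and 50.8% in cells with at most 10% mitochondrial UMIs. Each of these settings clustered the cells again. Clusters 1 and 2 held 0 called doublets, so the 35.6% reflects the new clusters and not the removal of doublets from the class. The secretory shares stayed within their intervals in all 6 alternatives.

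Reversed in the log2 values were Lyz1 (-0.059), Gcg (-0.015), the Goblet list (-0.030) and the Immune list (-0.013). Gcg reversed with thinned cells (-2.54) and without the cell with most of its UMIs (-2.87), and 98.3% of its UMIs at day 5 were in 1 cell. Without Enterocyte-like clusters, Dusp1 and the immediate early median reversed (both -0.12), and as a mean that list was -0.24. The Immune median was -1.66 with at least 50 UMIs, where 1 member remains, and the Villus tip median -0.77 with no minimum of UMIs. At least 50 UMIs left no member of the Stromal and endothelial list. Within Proliferating-like cells, with each library clustered alone the Proliferating, immediate early and p53 medians (-0.13, -0.44 and 0.58) were 0.052, 0.14 and -0.22. With doublets left out and the other cells clustered again, the immediate early and p53 medians were 0.073 and -0.026. The new clusters put 153 day 3 cells in this class instead of 213, although 2 day 3 doublets were called. Without the clusters led by Ero1l and Ankrd37 the immediate early median there was 0.15. Except where stated, the cause was not tested. At resolution 0.5 no day 3 cells were in that class, so no value was given. Depth limits genes under about 1 CPM, such as Olfm4 and Dclk1.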

Other observations

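Some of the tests below were chosen after the results they use had been seen. These were on dissociation stress and depth in clusters 11 and 12, on enterocyte numbers and on released RNA. The others were written first. Within day 3, clusters 11 and 12 (138 cells) were both led by Ero1l, Ankrd37 and Egln3, and cluster 11 also by Bnip3. Their gene programme was compared with the other 660 day 3 cells. Ndrg1, a stress-responsive gene, was at 273 CPM against 37.7, a log2 ratio of 2.86, Adm, which encodes adrenomedullin, had a ratio of 2.63, and Pgk1, a glycolytic kinase, one of 1.18. In cluster 12 the antioxidant gene Hmox1 and the stress gene Nupr1 were also among the leading genes, as were Trib3 and Ddit3, a member of the unfolded protein response list. Cluster 11 was also led by Mthfd2, Chac1 and Trib3. Stress programmes other than low oxygen and dissociation were not tested as explanations. The day 5 library held a cluster of 55 cells, when clustered alone, led by Clu, Msln and Anxa3, 5.16% of its cells (3.91 to 6.67). The joint clustering did not keep them together. It put 21 in cluster 3, 14 in cluster 5, 10 in cluster 9, 8 in the Clu-led cluster 4 and 2 in cluster 6. In these 55 cells, Ly6a was at 52.1 CPM against 1.26 in other day 5 cells, and S100a6 at 1029.2 against 181.

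A response to low oxygen may underlie clusters 11 and 12, a hypothesis found and tested on the same data, and no biological explanation that the design names was tested. Of 13 other hypoxia-inducible genes, 3 of them also in the Glycolysis list, all 12 measured members were higher in these clusters, with a median log2 ratio of 1.08 (1.01 to 1.17) at percentile 100 of random lists. Low depth as the cause was argued against for cluster 11, whose median UMI count was 0.933 of the day 3 median, but stays open for cluster 12 at 0.744 (0.877 together). Stress of dissociation stays open: the immediate early list had a median of 0.57 (0.45 to 0.76), with 5 members higher and the 3 heat shock members lower. Its criterion, at least 0.5, was tightened after this value was seen, so that the whole interval has to pass, and by the median alone it would be met.

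Reg1, Reg3a and Reg3b had 25, 0 and 10 UMIs at day 3 and Reg3g 339 (11.8 CPM), with 20 UMIs of the 4 genes in the 61 Enterocyte-like cells of that library against 94690 in 367 at day 5. Within these cells the summed Reg genes differed by 7.56 log2 units more than the Enterocyte list. A lower number of cells so named at day 3 was thus argued against as the whole cause. Fewer mature enterocytes were not, since the 61 and 367 cells are not alike. The joint clustering put only 3 day 3 cells in its Enterocyte-like clusters. Were released RNA the only source of day 5 Reg1, clusters would be alike, but the highest had 74.5 times the Reg1 of the lowest. Release beside expression is not excluded by this. A Reg1 UMI was seen in 86.0% of day 5 cells of Proliferating-like cluster 5 and 86.7% of those of mixed secretory cluster 10. With the day 3 UMI minimum applied to day 5, the log2 ratio of the summed genes was 7.36, against 9.24 in all cells. The enterocyte genes themselves had a median of 3.30 within these cells, so the day 3 cells may be less mature. Culture day and the removal of Wnt3a and Y-27632 could each account for this and were not told apart.

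The 55 Clu-high day 5 cells could be carried over from day 3. Over 100 genes that differ between days their summed UMIs sat at a median position of 0.974. There, 0 and 1 are the day 3 and day 5 Proliferating-like cells. Of the 55 cells, 14 lie in cluster 5, which makes up nearly all of the day 5 end, so the value is partly set by the choice of cells. It argues against carry-over of the 55 cells as a whole, but a sum cannot show whether a minority came from day 3. The 9 day 5 cells of joint cluster 4 sat at 0.696, with 62 of 100 genes nearer day 5. This fell just short of the position that the criterion written first asked for to argue against carry-over. Their median UMI count was 2.34 times that of the day 5 library. For these 9 cells carry-over therefore stays open, as do doublets. Doublets stay a candidate explanation: the 55 cells had 1.83 times the median UMIs of their library, which met the criterion written first. Of the 6 called day 5 doublets, 4 were among them, and the joint clustering spread the 55 cells over several clusters. The Proliferating-like cells of cluster 5 had 1.56 times that median, so high counts alone do not mark doublets. A persisting regenerative state, with the day of culture as the design's factor, was not tested.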
